A study of Mus musculus with 16 samples.

How the data were processed

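RNA had been extracted from isolated glomeruli and renal cortex of control and HFD/STZ-diabetic mice with the Qiagen RNeasy Plus Mini kit, and libraries had been made from 1.3 µg of total RNA with the SMARTER mRNA-Seq kit, per the labels' protocols. The labels put the 16 libraries in 4 groups of 4, all of wild-type mice aged 24 weeks and of batch 1. They number the libraries of each group but do not say that they came from separate animals, so p-values measure only the spread between these samples, which may be technical. The submitters' processing notes name the builds GRCm38 and mm10. The aligner, the counting tool and the gene annotation are not given in the sources used here, nor is whether counting used strand, so genes that share reads with close copies or overlapping genes (immunoglobulin, class II and Cyp4a genes among those named) are uncertain.

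The authors deposited a table of raw read counts per gene symbol for the glomeruli, whose values were whole numbers. For the cortex the authors deposited whole numbers per Ensembl gene identifier which, from the values, were estimated counts made whole: the FPKM value of a gene per count was not constant at low counts, and 15 values above 0 had an FPKM of 0. They were used as whole numbers with no further rounding. For each tissue the authors also deposited FPKM values, which divide by gene length and library size and were used as an alternative. The glomerular table held 24722 genes and no gene at 0 in every library, and the cortex table held 34264, of which 2568 were at 0 in every library. Names and positions were taken from GENCODE release M21 on GRCm38. Of the glomerular symbols 19796 matched directly and 322 through synonyms, and 4604, with 3.99% of the counts, did not match. Of the cortex identifiers 31953 matched and 2311, with 0.32% of the counts, did not. The tables joined at 19050 genes. Because they were made on different annotations and with different counting, levels of a gene in glomeruli and cortex can differ for that reason alone. The difference of the diabetic effect between tissues cancels any factor that multiplies a gene alike in all libraries of a table.

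Before libraries were averaged, each pair within a group was compared by a chi-square test of counts over genes. Every pair differed by this test. However, 2 pairs of glomerular libraries had a chi-square per gene below that of all other pairs of their own group by a factor of more than 5 (control 3 and 4, 2.82, and diabetic 1 and 4, 7.05). The counts of each pair were summed and used as 1 sample. The factor was set after the data were seen, and the step departs from the design fixed before the data were examined, which had 4 against 4 glomerular libraries. That design was kept as an alternative.

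Genes were tested with edgeR 4.0.16 (R 4.3.3): low counts removed with filterByExpr, TMM scaling, glmQLFit with robust dispersion and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each tissue was fitted alone. The difference of the diabetic effect and the contrast of control glomeruli with control cortex were fitted in 1 model of the 4 groups on the joined genes. Means and SDs are of CPM on TMM-scaled library sizes, and a group without counts was set against a floor of 3 counts over the group. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Gene lists (28) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with an inter-gene correlation of 0.01 and adjustment over all lists with at least 3 genes. An estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were run beside it. With an estimated correlation none of these lists was called in any comparison. Overlap of calls was tested with Fisher's exact test, two-sided, per direction.

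The genes named were chosen by a rule fixed before the data were examined: Nsd2, Nsd1, Nsd3, Setd2, Yap1, Wwtr1, Lats1 and Lats2, called or not; the 10 largest increases and 10 largest decreases among called genes with a mean log2 CPM of at least 1 and groups that did not overlap, leaving out predicted genes named with Gm and a number, names ending in Rik and genes without a symbol (5 and 5 for comparisons between tissues); and up to 4 members of each list with the smallest adjusted p (cell type lists alone between tissues). The lists covered markers of podocytes, mesangial, endothelial, smooth muscle and renin cells, proximal tubule, distal nephron and collecting duct, macrophages, lymphocytes, adipocytes, red blood cells and adrenal cortex, sex-linked genes, H3K36 methylation enzymes, Hippo components, YAP and TAZ targets, extracellular matrix, tubular injury, inflammatory and interferon genes, fatty acid oxidation, cholesterol and fatty acid synthesis, oxidative phosphorylation, glucose handling, antioxidant genes, the unfolded protein response, cell cycle, immediate early and heat shock genes, and clock genes. Lists shared members (Ccl2 and Cxcl10, for example, stood in several), and markers were not exclusive to a cell type. The sex-linked, immediate early and heat shock, and clock lists had been fixed as checks of mice, handling and collection time. Values of some genes that the rule named are not reported here.

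The procedure was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by 1.5, 2 or 4-fold (seed 7). In the glomerular design edgeR recovered 7.46, 43.3 and 84.8% of the genes at these sizes among 15238 genes, with 13 unchanged genes called. In cortex edgeR recovered 26.9, 52.2 and 81.8% among 19228 (7 unchanged among 114 called). For the difference between tissues the shares were 10.4, 37.3 and 74.2% (3 unchanged called) and for the tissue contrast 17.9, 59.7 and 81.8% (5 unchanged called), each among 16512 genes. DESeq2 recovered more in the glomerular design (37.3, 70.1 and 95.5%), but 61 of the 196 genes it called were unchanged, a larger share than with edgeR. A simulated list of 20 genes was called by camera in both tissues and no other list was. Simulated genes were drawn independently of one another, so this cannot show how often camera calls lists whose genes move together.

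Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper-quartile scaling, library totals, no filter on low counts, a CPM of at least 1 in at least 4 libraries, the replicate number as a block, the 4-group model, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean FPKM of at least 0.5 and without that filter, an absolute log2 fold change of at least 1, each library left out in turn, no robust dispersion, and 1 surrogate variable from sva 3.50.0. The 8 separate glomerular libraries, the design fixed beforehand, became an alternative once the pairs had been summed. Alternatives chosen after the data were seen were both libraries of each near-identical pair left out, diabetic glomerular libraries 1, 3 and 4 left out, and cortex control libraries 3 and 4 left out. All splits of the samples were fitted, the real one included (10 for glomeruli, 35 for cortex and for the tissue contrast), and 60 with the real one were used for the difference between tissues (drawn with seed 11). Further computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.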

Results

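RNA was sequenced from isolated glomeruli (the filtering tufts of the kidney, made of podocytes, endothelial and mesangial cells) and from renal cortex of 24-week-old wild-type mice. Diabetes had been induced with a high-fat diet and streptozotocin (HFD/STZ), a toxin of the insulin-producing beta cells, and the controls were not diabetic. The groups do not separate effects of the diet, of streptozotocin and of the diabetic state. An effect of diabetes below stands for all of these together. Each tissue had 4 control and 4 diabetic libraries, 16 in all. Total counts per library were 40001932 to 41876031 in control glomeruli and 36339294 to 40696477 in diabetic glomeruli. They were 57473100 to 69947387 in control cortex and 60628981 to 72352656 in diabetic cortex. In the glomeruli, control libraries 3 and 4 and diabetic libraries 1 and 4 were more than 5 times closer to each other than any other pair of their group (chi-square per gene 2.82 against 48.7 to 90.4, and 7.05 against 70.8 to 105). Each of these pairs was summed and counted as 1 sample after the data were seen. This left n = 3 control and n = 3 diabetic glomerular samples, against n = 4 of each in cortex. Values are CPM (counts divided by the effective library size and scaled to 1e6), as mean ± SD of samples. Log2 fold changes are diabetic against control and are given ± SE.

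The series asks, by its title, whether the histone methyltransferase NSD2 acts on podocytes through Hippo signalling, so these genes were examined first. In glomeruli, Nsd2, which encodes an enzyme that dimethylates lysine 36 of histone H3 (GRCm38 chromosome 5, 33820725 to 33897975), rose from 33.3 ± 5.98 CPM in control to 73.0 ± 3.60 CPM in diabetic samples (n = 3 each). Its log2 fold change was 1.13 ± 0.14 (adjusted p = 0.00182, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The highest control sample was at 38.1 CPM and the lowest diabetic sample at 69.2 CPM. The related enzymes Nsd1 (0.21 ± 0.20, adjusted p = 0.426), Nsd3 (-0.05 ± 0.09, 0.708) and Setd2 (0.34 ± 0.27, 0.352) did not pass the edgeR test. Of the 12 genes in the list of enzymes that write or erase H3K36 methylation, 1 was called higher (Nsd2) and 1 lower (the demethylase Kdm4b, -0.59 ± 0.10). These counts were the same when adjusted over the list alone, and the list was not called (camera adjusted p = 0.691). With library totals in place of TMM 4 rose and 1 fell, and with log2(FPKM + 1) 3 and 1.

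The Hippo effectors were lower in diabetic glomeruli. Yap1, a transcriptional co-activator held in check by the Hippo kinases (chromosome 9, 7931999 to 8004596), fell from 279 ± 53.4 to 185 ± 5.10 CPM (log2 -0.60 ± 0.14, edgeR adjusted p = 0.0170). Its paralog Wwtr1, which encodes TAZ (chromosome 3, 57455649 to 57575910), fell from 289.6 ± 21 to 196 ± 26.7 CPM (-0.56 ± 0.12, 0.0123). The kinase gene Lats2 (chromosome 14, 57689662 to 57758388), itself a target of YAP, fell from 316 ± 50.4 to 179 ± 21.4 CPM (-0.82 ± 0.15, edgeR adjusted p = 0.00634), whereas Lats1 did not pass the test (0.13 ± 0.17, 0.563). Of the 28 Hippo pathway components, 4 rose and 11 fell (6 and 12 when adjusted over the list alone). Those that rose included Wwc1, which encodes the upstream activator KIBRA, from 35.6 ± 2.59 to 285 ± 81.2 CPM, and the scaffold genes Amot (1.31 ± 0.16) and Amotl1 (0.89 ± 0.12). The transcription factor gene Tead3 fell (-0.85 ± 0.09). The list went both ways and was not called (camera adjusted p = 0.224). Leaving out diabetic libraries 1, 3 and 4 gave 5 higher and 2 lower (median log2 -0.19 against -0.23), and library totals in place of TMM gave 7 higher and 8 lower.

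**Figure D1:**
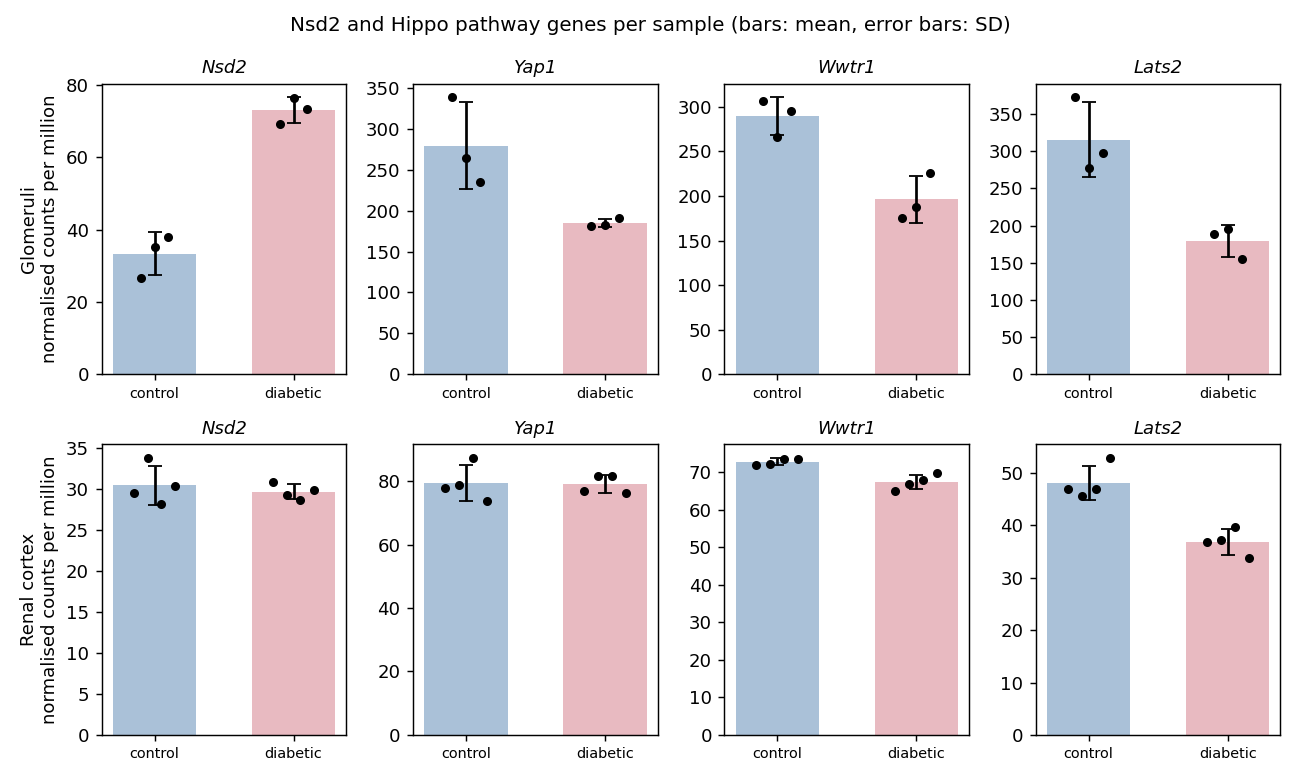
CPM of Nsd2, Yap1, Wwtr1 and Lats2 in glomeruli (top, n = 3 per group) and cortex (bottom, n = 4 per group), with control and diabetic groups on the x axis. Bars are group means, error bars the SD and dots single samples. The 3 diabetic glomerular samples lie above all control samples for Nsd2, at 69.2 CPM or higher, and below them for the other genes. The cortex groups lie close together for Nsd2 (means of 30.4 and 29.7 CPM).

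Of 22 target genes of YAP and TAZ, 14 fell and 2 rose in diabetic glomeruli (the same when adjusted over the list alone). Smooth muscle markers, matrix genes and mesangial markers had medians of -2.05, -1.28 and -0.54 in the same samples, beside -0.62 for these targets. In control mice 20 of the 22 targets were called higher in glomeruli than in cortex. The list was called lower (camera adjusted p = 0.00412; adjusted p = 0.894 with an estimated correlation). Ccn2, which encodes connective tissue growth factor, fell from 8221 ± 646 to 3541 ± 332 CPM (-1.22 ± 0.14, edgeR adjusted p = 0.00137). Igfbp3 fell from 129 ± 13.5 to 33.1 ± 3.89 CPM and Crim1 from 1323 ± 271 to 444 ± 41.1 CPM. Leaving out diabetic libraries 1, 3 and 4 gave 2 higher and 5 lower, with a median of -0.55.

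Most smooth muscle markers and matrix genes were called lower in diabetic glomeruli, as were part of the podocyte and mesangial markers. Of 36 podocyte markers, 16 fell, 2 rose and 18 did not pass, also when adjusted over the list alone (camera adjusted p = 0.000631; adjusted p = 0.894 with an estimated correlation). Lmx1b, a transcription factor of podocyte differentiation, fell from 88.4 ± 8.85 to 42.3 ± 0.263 CPM (-1.07 ± 0.09, edgeR adjusted p = 0.000692). Foxc2 fell from 111 ± 20.3 to 43.3 ± 0.669 CPM (-1.36 ± 0.14) and Kirrel, which encodes the slit diaphragm protein NEPH1, from 575 ± 68.9 to 242 ± 35.5 CPM (-1.25 ± 0.15). Of 14 mesangial markers 5 fell and 0 rose by edgeR (0 also by DESeq2 and at an unadjusted p under 0.05), with the same counts when adjusted over the list alone (camera adjusted p = 0.00298; adjusted p = 0.894 with an estimated correlation). Among them the growth factor receptor gene Pdgfrb fell from 462 ± 84.1 to 119.9 ± 10.9 CPM. Smooth muscle and renin cell markers fell in 8 of 10 cases (camera adjusted p = 0.000631; adjusted p = 0.410 with an estimated correlation; the same count when adjusted over the list alone). In control glomeruli, 24 of 28 muscle and matrix genes called higher than in cortex stood above the level that glomeruli at their share of cortex RNA, estimated from podocyte markers, would allow. Myh11, the smooth muscle myosin heavy chain, was at 291 ± 54.0 and 19.1 ± 3.64 CPM and Tagln at 7391 ± 1008 and 1789 ± 517 CPM in control and diabetic samples.

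Of 24 extracellular matrix and fibrosis genes, 15 fell and 0 rose by edgeR (1 higher by DESeq2 and at an unadjusted p under 0.05; 1 higher and 16 lower when adjusted over the list alone; camera adjusted p = 1.86e-05; adjusted p = 0.894 with an estimated correlation). Col4a2, a chain of basement membrane collagen, fell from 3582 ± 283 to 1065 ± 204 CPM (-1.75 ± 0.17, edgeR adjusted p = 0.000850). The proteoglycan genes Bgn and Dcn fell as well (-2.46 ± 0.24 and -3.55 ± 0.28). With diabetic libraries 1, 3 and 4 left out, library 2 stood alone and was assumed to vary like the controls. Calls were then 0 higher and 15 lower among the matrix genes and 1 higher and 7 lower among smooth muscle markers. They were 2 higher and 5 lower among podocyte markers (median -0.34 against -0.53) and 0 higher and 2 lower among mesangial markers (-0.54 against -0.54).

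Tubule markers were higher in diabetic glomeruli, mainly in diabetic samples 1+4 and 3. Of 25 proximal tubule markers 17 rose (22 when adjusted over the list alone; median log2 3.11; camera adjusted p = 0.000455; adjusted p = 0.894 with an estimated correlation). Of 18 distal nephron and collecting duct markers 15 rose (18 when adjusted over the list alone; median 3.77; camera adjusted p = 0.000205; adjusted p = 0.894 with an estimated correlation). Lrp2, which encodes the endocytic receptor megalin, was at 5.86 ± 0.922 CPM in control samples and at 121, 23.5 and 73.6 CPM in diabetic samples 1+4, 2 and 3 (edgeR adjusted p = 0.00437). Slc6a19, a neutral amino acid transporter of the brush border, was at 0.698 ± 0.131 CPM and at 20.9, 1.30 and 10.1 CPM. The sex-linked transcript Xist stood at 9.65 ± 2.87 CPM in controls and at 61.8, 7.53 and 25.6 CPM in the same diabetic samples, and did not pass the test (1.72 ± 0.69, edgeR adjusted p = 0.0938). Leaving out diabetic libraries 1, 3 and 4 gave 2 higher and 0 lower among proximal markers and 4 higher and 0 lower among distal markers, with medians of 0.13 and 0.36, and neither list was then called (camera adjusted p = 0.313 and 0.0513). With log2(FPKM + 1) in place of counts 3 of 24 proximal and 6 of 17 distal markers were called higher. With control libraries 3 and 4 left out these were 2 of 25 and 5 of 20, while the medians stayed at 2.94 and 3.72.

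Genes of tubular injury were split in diabetic glomeruli, with 7 of 19 higher and 3 lower (8 and 3 when adjusted over the list alone; camera adjusted p = 0.0503, not called). Clu, which encodes the secreted chaperone clusterin, rose from 57.9 ± 42 to 3089 ± 274 CPM (5.74 ± 0.56, edgeR adjusted p = 0.000957). Sox9, a transcription factor of tubule repair, rose from 7.20 ± 2.54 to 46.2 ± 6.15 CPM, and Krt20 from 0.227 ± 0.0916 to 27.6 ± 9.44 CPM. The complement gene C3 fell from 172 ± 51.7 to 14.4 ± 4.82 CPM (-3.58 ± 0.34). Clu did not follow the tubule markers across diabetic samples, at 3019, 3391 and 2856 CPM in samples 1+4, 2 and 3. Over the 7 higher genes the median rise above controls was 476, 515 and 345% of the diabetic cortex level in these samples. Single genes among them may differ from this median. Leaving out diabetic libraries 1, 3 and 4 gave 6 higher and 3 lower, log2(FPKM + 1) 11 and 3, and the 8 separate libraries 11 and 4.

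Part of the macrophage and myeloid markers, glucose handling and antioxidant genes were called higher, beside the tubule markers of samples 1+4 and 3. Of 22 myeloid markers 8 rose and 1 fell (11 and 1 when adjusted over the list alone; camera adjusted p = 0.0168; adjusted p = 0.906 with an estimated correlation). The invariant chain gene Cd74 was at 5.76 ± 2.38 CPM in controls and 77.9, 28.4 and 107 CPM in diabetic samples 1+4, 2 and 3. By contrast, the abundant myeloid gene Lyz2 went from 374 ± 185 to 112 ± 69.7 CPM, on the scaling of the 4-group model. Of 22 glucose handling genes 12 rose and 0 fell by edgeR (0 also by DESeq2 and at an unadjusted p under 0.05), with the same counts when adjusted over the list alone (camera adjusted p = 0.00827; adjusted p = 0.894 with an estimated correlation). Akr1b3, the aldose reductase of the polyol pathway, rose from 117 ± 16.5 to 295 ± 21.5 CPM and Hk2, a hexokinase, from 29.7 ± 13.3 to 123 ± 20.4 CPM. The transporter gene Slc2a2 followed the tubule markers (12.6, 0.731 and 7.08 CPM in samples 1+4, 2 and 3). Of 21 antioxidant and NADPH oxidase genes 9 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0183; adjusted p = 0.894 with an estimated correlation). Osgin1 rose from 2.21 ± 0.457 to 29.7 ± 1.22 CPM. Without diabetic libraries 1, 3 and 4 the calls were 1 higher and 0 lower among myeloid markers, 2 higher and 2 lower among glucose genes and 2 higher and 2 lower among antioxidant genes. Their medians were 0.51, 0.17 and 0.34, against 1.34, 1.14 and 0.47, and none of these lists was called (camera adjusted p = 0.236, 0.358 and 0.236). The myeloid and antioxidant lists were also not called without diabetic library 3 (camera adjusted p = 0.0685 and 0.0561) or with library totals (0.101 and 0.0524). With control libraries 3 and 4 left out 2 myeloid, 2 glucose and 5 antioxidant genes were called higher (medians 0.90, 1.06 and 0.38), and with log2(FPKM + 1) 5 of 21 glucose genes.

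Of 30 oxidative phosphorylation genes 5 rose in diabetic glomeruli (4 when adjusted over the list alone; median log2 0.20; camera adjusted p = 0.0446; adjusted p = 0.923 with an estimated correlation). The number higher was 18 with library totals, 18 with log2(FPKM + 1) and 15 with the 8 separate libraries, and 2 with diabetic libraries 1, 3 and 4 or control libraries 3 and 4 left out (medians 0.08 and 0.15). The list was not called without diabetic libraries 1, 3 and 4 (camera adjusted p = 0.443) or without control library 2 (0.199). Mitochondrial transcripts made up 5.64, 2.70, 4.02 and 5.27% of counts in diabetic libraries 1, 2, 3 and 4, against 2.37 to 2.98% in controls. The other glomerular lists were not called by camera. Fatty acid oxidation genes had 6 higher and 1 lower of 25, and cholesterol and fatty acid synthesis 5 and 5 of 23. The unfolded protein response had 3 higher and 2 lower of 18 (among the higher ones the stress gene Chac1, 2.03 ± 0.17). Immediate early and heat shock genes had 1 and 4 of 23, the interferon response 1 and 2 of 24, and inflammatory genes 1 and 1 of 20. Cell cycle genes had 4 and 1 of 23, and clock genes 2 and 3 of 17. When adjusted over the list alone these were 5 and 1, 5 and 5, 3 and 2, 1 and 4, 0 and 0, 0 and 0, 1 and 0, and 2 and 2. With library totals there were 6 higher and 1 lower for cholesterol and fatty acid synthesis, 7 and 1 for the unfolded protein response, 9 and 0 for cell cycle and 4 and 2 for clock genes. With the 8 separate libraries there were 10 higher and 2 lower for fatty acid oxidation, 1 and 3 for inflammatory, 3 and 3 for interferon, 6 and 5 for cell cycle and 3 and 6 for clock genes. Without diabetic libraries 1, 3 and 4 there were 0 higher and 1 lower for fatty acid oxidation, 2 and 0 for cholesterol synthesis, 1 and 0 for immediate early, 0 and 0 for cell cycle and 1 and 1 for clock genes. Endothelial markers had 1 lower of 22 (Lpl) and none when adjusted over the list alone. Adipocyte markers had 1 lower of 2 (Retn), lymphocyte markers 1 higher of 5 (Lck) and adrenal cortex markers 1 higher of 4 (Cyp21a1), each also when adjusted over the list alone. Of 6 red blood cell and 5 sex-linked genes edgeR called 0, also when adjusted over the list alone, while 1 of each passed an unadjusted p under 0.05 and DESeq2 called 1 and 0. The median, mean and test of a list differed in sign for the unfolded protein response (median -0.00, mean 0.23, test higher), cholesterol synthesis (-0.01, 0.15, lower) and the clock genes (-0.32, 0.02, lower). The medians of the endothelial, cholesterol synthesis and unfolded protein response lists changed sign when library totals or FPKM replaced the TMM scaling. Control sample 2 stood apart for the chemokine genes Ccl2 and Ccl7, Ccl7 being at 117 CPM against at most 6.35 CPM in the other controls.

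Across 15238 genes tested in glomeruli, 5717 were called, 2950 higher and 2767 lower (edgeR, adjusted p under 0.05), and 7786 were called when the 8 libraries were kept separate as designed. With library totals in place of TMM, 72.6% of calls were higher rather than 51.6%, and the median log2 fold change of all genes moved from 0.01 to 0.20. With FPKM values, 69.1 to 72.2% were higher. The groups did not overlap for 8262 genes (54.2%, where chance gives 10% with 3 against 3) and for 5632 of those called. Among well-expressed genes the largest increases included Entpd3, an ectonucleotidase gene (chromosome 9, 120539818 to 120568327), with no count in controls and 6.05 ± 1.38 CPM in diabetic samples. It was at least 329-fold higher against a floor of 3 counts over the control group. Others were Plekhs1 (0.0261 ± 0.0265 and 50.9 ± 26.1 CPM), the serine protease gene Prss22 (0.251 ± 0.333 and 91.7 ± 33.2 CPM), AI593442 (0.0486 ± 0.0336 and 29.4 ± 4.26 CPM) and the chemokine gene Ccl24 (1 count in controls, 6.55 ± 5.20 CPM). Large decreases included the collagen-binding integrin gene Itga11 (203 ± 99.9 and 8.97 ± 0.519 CPM), the progesterone receptor gene Pgr (27.3 ± 11.8 and 1.23 ± 0.352 CPM), Slc1a6 (8.56 ± 0.729 and 0.265 ± 0.103 CPM) and Cbr2 (18.5 ± 2.50 and 1.09 ± 0.153 CPM). With diabetic libraries 1, 3 and 4 left out, 2293 genes were called, 1356 higher and 937 lower.

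In cortex, Nsd2 was at 30.4 ± 2.37 CPM in control and 29.7 ± 0.934 CPM in diabetic mice (n = 4 each; log2 -0.04 ± 0.07, edgeR adjusted p = 0.757). Yap1 (-0.01 ± 0.06, 0.963) and Wwtr1 (-0.11 ± 0.05, 0.128) did not pass either. The kinase genes Lats1 (-0.37 ± 0.07, edgeR adjusted p = 0.00583) and Lats2 (-0.39 ± 0.07, 0.00458) fell, as did Nsd1 (-0.21 ± 0.05, 0.0197). Nsd3 (-0.21 ± 0.08, 0.0823) and Setd2 (-0.24 ± 0.08, 0.0647) did not pass the edgeR test. Of 28 Hippo components 5 fell and 0 rose by edgeR (0 also by DESeq2 and at an unadjusted p under 0.05), with the same counts when adjusted over the list alone (camera adjusted p = 0.0522, not called). Amot (-0.50 ± 0.09) and Mob1b (-0.32 ± 0.07) were among them. Of 21 YAP and TAZ targets 5 rose, including the matricellular gene Ccn1 from 27.7 ± 3.52 to 84.4 ± 20.5 CPM and F3, which encodes tissue factor (0.86 ± 0.12), and 4 fell (9 and 4 when adjusted over the list alone). That list was not called (camera adjusted p = 0.697), with a median of -0.09 and a mean of 0.18, and 4 rose and 2 fell with library totals (5 and 2 with log2(FPKM + 1) and 5 and 2 without control libraries 3 and 4). Among H3K36 enzymes 1 rose (Smyd2) and 3 fell (1 and 5 when adjusted over the list alone; camera adjusted p = 0.115, not called). With library totals or log2(FPKM + 1) they numbered 1 and 0.

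Immune and interferon genes rose in diabetic cortex. Of 25 interferon response genes 24 rose and 0 fell by edgeR (0 also by DESeq2 and at an unadjusted p under 0.05; 25 higher when adjusted over the list alone; median log2 1.25; camera adjusted p = 6.25e-17; adjusted p = 0.225 with an estimated correlation). Cxcl10, a chemokine induced by interferon (chromosome 5, 92346638 to 92348889), rose from 3.30 ± 0.389 to 31.0 ± 5.92 CPM (3.23 ± 0.15, edgeR adjusted p = 5.99e-06). Bst2, which encodes tetherin, rose from 9.99 ± 2.61 to 44.9 ± 11.5 CPM. Myeloid markers rose in 18 of 23 cases (20 when adjusted over the list alone; camera adjusted p = 6.03e-14; adjusted p = 0.222 with an estimated correlation). The class II gene H2-Ab1 rose from 50.9 ± 10.8 to 171 ± 35.3 CPM. Lymphocyte markers rose in 10 of 17 (12 when adjusted over the list alone; 5.39e-08; adjusted p = 0.205 with an estimated correlation). The immunoglobulin light chain gene Igkc rose from 5.60 ± 1.54 to 95.4 ± 18.1 CPM. The heavy chain gene Ighg1 had no count in controls and 5.30 ± 4.09 CPM in diabetic mice, at least 450.2-fold higher against a floor of 3 counts over the group. Immunoglobulin genes resemble one another, and how shared reads were counted is not given in the sources used here. Inflammatory and NF-kB target genes rose in 13 of 18 (15 when adjusted over the list alone; camera adjusted p = 7.75e-11; adjusted p = 0.205 with an estimated correlation). Ccl2, the monocyte chemoattractant, rose from 0.257 ± 0.0861 to 4.05 ± 1.23 CPM and Icam1 from 15.1 ± 2.55 to 46.2 ± 8.77 CPM.

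Tubular injury genes rose in 16 of 21 cases in diabetic cortex (17 when adjusted over the list alone; median log2 1.33; camera adjusted p = 1.12e-11; adjusted p = 0.222 with an estimated correlation). Havcr1, which encodes the injury marker KIM-1 (chromosome 11, 46735080 to 46779578), rose from 1.65 ± 0.962 to 40.4 ± 20.9 CPM (4.59 ± 0.57, edgeR adjusted p = 0.00207). Cdkn1a, the cell cycle inhibitor p21, rose from 11.9 ± 4.79 to 140.0 ± 15.1 CPM. Immediate early and heat shock genes rose in 16 of 23 (17 higher and 1 lower when adjusted over the list alone; camera adjusted p = 6.75e-09; adjusted p = 0.222 with an estimated correlation). Nr4a1 rose from 9.32 ± 1.68 to 75.4 ± 25.9 CPM. That list had been fixed beforehand as a check of handling, and it differed between the cortex groups. A difference in handling cannot be told from an effect of diabetes here, which also bears on other stress and inflammatory genes in cortex. Of 23 cell cycle genes 10 rose and 1 fell (18 and 1 when adjusted over the list alone; 6.61e-06; adjusted p = 0.229 with an estimated correlation). Of 18 unfolded protein response genes 6 rose (9 and 1 when adjusted over the list alone; 0.000355; adjusted p = 0.229 with an estimated correlation). Matrix genes had 5 higher, including Col4a1 (0.49 ± 0.08) and Mmp2 (1.91 ± 0.32), and 1 lower of 25 (9 and 1 when adjusted over the list alone; 0.00576; adjusted p = 0.589 with an estimated correlation). The matrix list was not called without control library 2 (camera adjusted p = 0.128).

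Proximal tubule markers fell in 13 of 25 cases in diabetic cortex (17 when adjusted over the list alone; camera adjusted p = 6.17e-07; adjusted p = 0.245 with an estimated correlation). Slc5a12, a lactate transporter, fell from 244 ± 36.3 to 110.2 ± 12.4 CPM and Miox, an inositol oxygenase, from 1855 ± 427 to 872 ± 75.8 CPM. Control library 4 was lower than the other controls for Miox, at 1218 CPM against 2008 CPM or more. Distal markers had 7 lower and 1 higher (Pvalb) of 20, also when adjusted over the list alone (0.00557; adjusted p = 0.229 with an estimated correlation). Cholesterol and fatty acid synthesis genes fell in 15 of 23 and rose in 1 (16 and 1 when adjusted over the list alone; camera adjusted p = 6.27e-07; adjusted p = 0.169 with an estimated correlation). The desaturase gene Scd2 (-0.85 ± 0.10) and Idi1 (-0.75 ± 0.12) were among those that fell. Fatty acid oxidation and PPARA target genes rose in 8 of 27 and fell in 1 (9 and 1 when adjusted over the list alone; 0.0286; adjusted p = 0.393 with an estimated correlation), a list not called without control library 1 (camera adjusted p = 0.0953). Acaa1b, a peroxisomal thiolase, rose from 256 ± 10.4 to 318 ± 18.0 CPM (0.31 ± 0.06, edgeR adjusted p = 0.00780). Among glucose handling genes Pck1, the gluconeogenic enzyme PEPCK, rose (1.09 ± 0.16, edgeR adjusted p = 0.00187), and 3 of 21 fell, including Slc5a2, which encodes the glucose transporter SGLT2 (-1.01 ± 0.20). The counts were 1 and 4 when adjusted over the list alone (camera adjusted p = 0.697, not called), and 4 and 4 over all genes without control libraries 3 and 4. Red blood cell markers fell in 6 of 6 cases, also when adjusted over the list alone (1.41e-05; adjusted p = 0.229 with an estimated correlation), and in 2 without control libraries 3 and 4, where the median was -1.09 against -1.11. Hbb-bs fell from 321 ± 71.4 to 135 ± 29.6 CPM.

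Smooth muscle markers had 2 lower of 8 in cortex (3 when adjusted over the list alone; camera adjusted p = 0.0286; adjusted p = 0.229 with an estimated correlation). They were not called without control library 3 (0.0636), 4 (0.0850) or both (camera adjusted p = 0.280). Podocyte markers had 7 lower, among them Ddn (-0.73 ± 0.10), and 1 higher of 35 (1 and 10 when adjusted over the list alone; 0.0527, not called). The lower calls among podocyte markers depended on the scaling, as library totals gave 2 higher and 2 lower and log2(FPKM + 1) gave 1 higher and 2 lower. Without control libraries 3 and 4 they were 3 higher and 6 lower. The lists not called by camera also included oxidative phosphorylation (6 higher and 1 lower of 30), antioxidant genes (5 and 2 of 22), and mesangial (2 and 1 of 14) and endothelial markers (1 and 1 of 22). Clock genes were not called either (2 and 3 of 17, with a median of 0.03, a mean of 0.07 and a test towards lower). Adjusted over the list alone, these were 6 and 1, 5 and 3, 2 and 1, 0 and 0, and 2 and 3. Oxidative phosphorylation had 10 higher with library totals, 11 with log2(FPKM + 1) and 3 without control libraries 3 and 4, which also gave 4 higher and 0 lower for endothelial markers. Clock genes had 1 higher and 1 lower with library totals. The sex-linked list had 1 lower of 5 (Uty) and the adipocyte list 1 lower of 3 (Car3), each also when adjusted over the list alone. Of 3 adrenal markers edgeR called 0, also when adjusted over the list alone (1 at an unadjusted p under 0.05, 0 by DESeq2). The adipocyte genes Cidec and Plin4 stood apart in control library 3, at 22.3 and 22.9 CPM. The medians of the mesangial and glucose handling lists changed sign with FPKM.

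Across 19228 genes tested in cortex, 3856 were called, 2069 higher and 1787 lower (edgeR), and the groups did not overlap for 4795 genes (24.9%, where chance gives 2.86%). With library totals in place of TMM, 63.5% of calls were higher rather than 53.7%. Large increases besides the immunoglobulin genes were Eda2r, a receptor of the tumour necrosis factor family (0.371 ± 0.130 and 10.8 ± 1.07 CPM), Psrc1 (0.321 ± 0.0593 and 8.80 ± 1.69 CPM) and the neutrophil chemokine gene Cxcl1 (0.628 ± 0.436 and 26.4 ± 15.4 CPM). Large decreases were the transcription factor gene Osr2 (10.0 ± 1.59 and 1.26 ± 0.217 CPM), Ces1g (41.4 ± 10.8 and 8.13 ± 2.77 CPM), the desaturase gene Scd1 (348 ± 215 and 70.1 ± 19 CPM) and coagulation factor gene F5 (9.23 ± 1.45 and 2.51 ± 0.434 CPM). The count fell to 2528, 2538 and 2542 without diabetic libraries 2, 3 and 4 in turn.

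**Figure D2:**
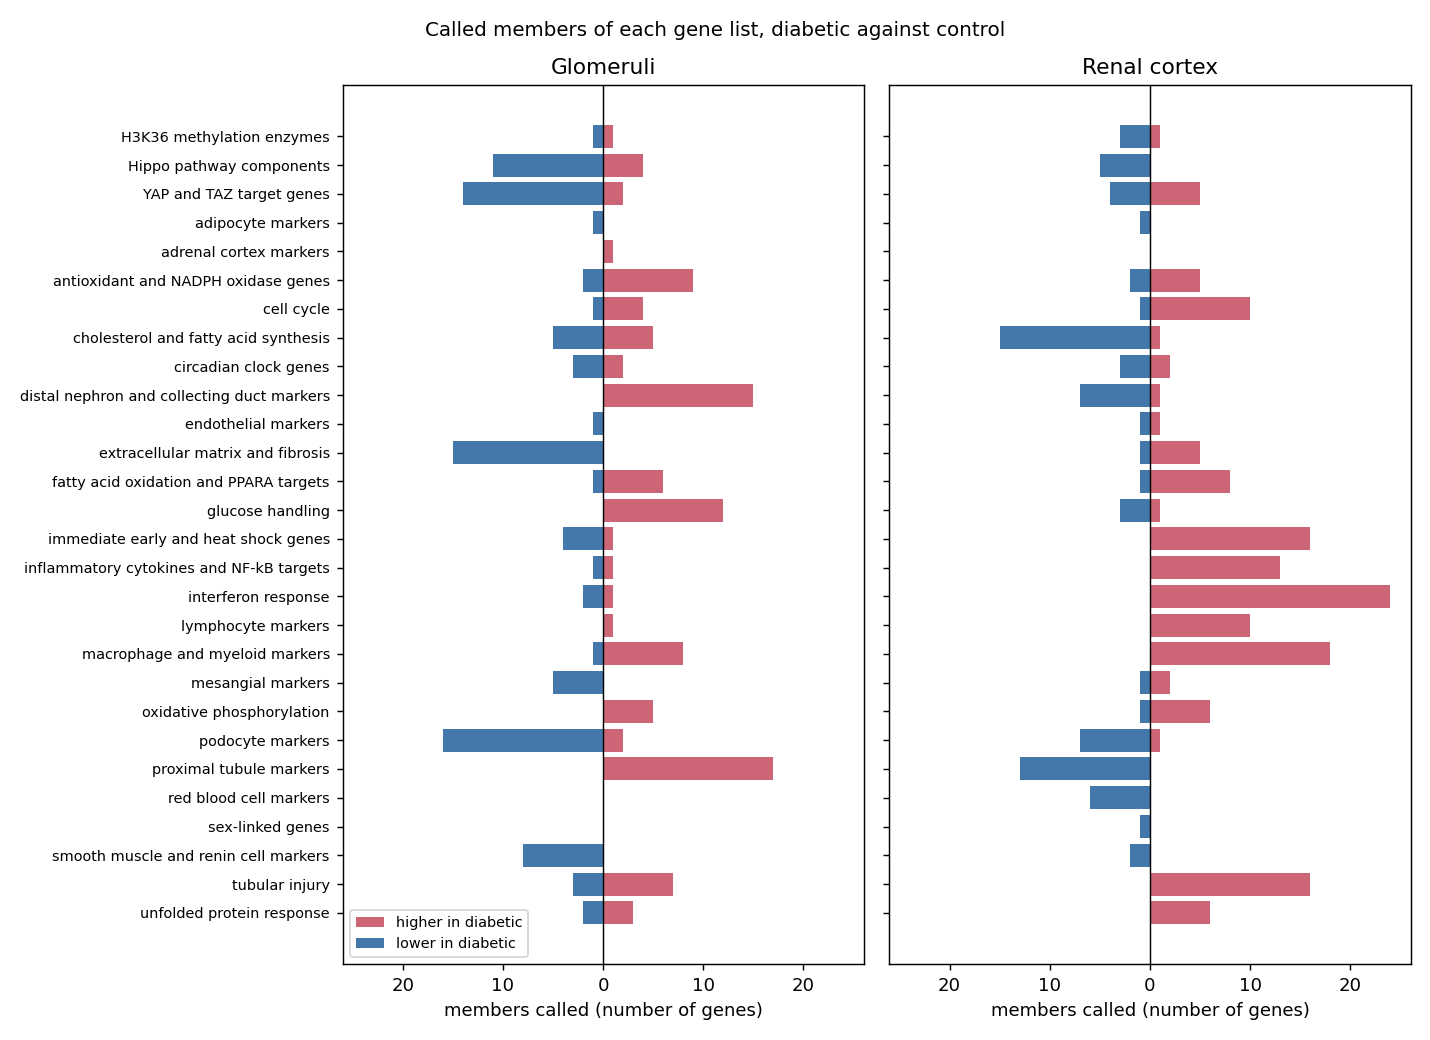
Number of genes of each list fixed before the data were examined that were called higher (bars to the right) or lower (bars to the left) in diabetic samples, by edgeR with Benjamini-Hochberg adjustment over all genes, in glomeruli and in cortex. The interferon list shows 24 higher in cortex and 1 in glomeruli, and the matrix list 15 lower in glomeruli and 1 in cortex.

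Whether the difference between diabetic and control mice was unlike in glomeruli and cortex was tested as an interaction (glomeruli minus cortex). This test took the samples of the tissues as independent, and the labels do not say whether they came from the same mice. The diabetic effect on Nsd2 was higher in glomeruli by 1.17 ± 0.15 on the log2 scale (edgeR adjusted p = 7.17e-05). The effects on Yap1 (-0.59 ± 0.14, 0.00689), Wwtr1 (-0.45 ± 0.12, 0.0113) and Lats2 (-0.43 ± 0.15, 0.0464) were lower in glomeruli, and that on Lats1 was higher (0.51 ± 0.18, 0.0403). Differences for Nsd1 (0.42, 0.104), Nsd3 (0.17, 0.310) and Setd2 (0.58, 0.124) did not pass the edgeR test. Interferon response genes differed towards lower in glomeruli in 13 of 23 (camera adjusted p = 1.16e-05), immediate early genes in 17 of 23 (8.15e-07). Inflammatory genes did so in 10 of 20 (0.00135), lymphocyte markers in 4 of 14 (0.00927). Matrix genes did so in 18 of 25 with 1 the other way (1.72e-08) and podocyte markers in 15 of 36 with 2 the other way (0.00459). Proximal (24 of 25) and distal markers (20 of 20) differed towards higher in glomeruli (camera adjusted p = 2.73e-06 each), beside the tubule markers of diabetic samples 1+4 and 3. Adjusted over the list alone, these counts were 0 and 15, 0 and 17, 0 and 10, 0 and 4, 1 and 19, 2 and 15, 25 and 0, and 20 and 0, higher and lower. Each of these lists had an adjusted p = 0.472 with an estimated correlation. Of 16512 genes tested in both tables, 5786 differed, 3105 towards higher and 2681 towards lower in glomeruli (edgeR).

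The genes with the largest differences between tissues were near 0 in at least 1 group, where a fitted fold is no bound. Prss22 went from 0.252 ± 0.331 to 93.6 ± 32.9 CPM in glomeruli and stood at 0.125 ± 0.176 and 0 ± 0 CPM in cortex. Msln, which encodes mesothelin, went from 0.391 ± 0.256 to 85.8 ± 46.9 CPM in glomeruli and stood at 0.880 ± 1.05 and 0.281 ± 0.314 CPM in cortex. Itga11 went from 208 ± 104 to 9.17 ± 0.512 CPM in glomeruli and from 0.0311 ± 0.0622 to 0.689 ± 0.0383 CPM in cortex. Lyz2, which encodes a myeloid lysozyme, went from 374 ± 185 to 112 ± 69.7 CPM in glomeruli and from 15.8 ± 3.97 to 74.6 ± 23.7 CPM in cortex (interaction -3.98 ± 0.60, edgeR adjusted p = 0.000359), whereas Cd74 went the other way (2.14 ± 0.55, 0.00953).

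The control glomeruli were compared with control cortex to see how far they were enriched for glomerular cells. The tables of the tissues were counted differently, so this contrast mixes tissue with counting. No test told these apart for single genes such as Nupl1, at 81.1 ± 13.9 CPM in glomeruli and 0 ± 0 CPM in cortex, or Mettl7a2, at 0.00441 ± 0.00765 and 157 ± 95.0 CPM. Of 36 podocyte markers 35 were higher in glomeruli and 1 lower, also when adjusted over the list alone (median log2 2.95; camera adjusted p = 1.06e-09; adjusted p = 0.256 with an estimated correlation). Nes stood at 1547 ± 21.5 and 26.4 ± 2.86 CPM in glomeruli and cortex and Kirrel at 587 ± 80.7 and 16.2 ± 1.94 CPM. Mesangial markers were higher in 13 of 14 (0.000120) and endothelial markers higher in 10 and lower in 2 of 22 (0.122, not called). All 25 proximal and 20 distal tubule markers were called lower in glomeruli (camera adjusted p = 6.05e-09 and 2.14e-06), with Lrp2 at 5.97 ± 0.809 and 2464 ± 277 CPM. Smooth muscle markers were higher in 8 of 10 and lower in 2 (0.00284). Acta2, smooth muscle actin, stood at 9922 ± 547 and 35.2 ± 8.14 CPM. The matrix list had 21 of 25 higher (8.11e-07), the cell cycle list 23 of 23 (1.15e-07) and the immediate early list 22 of 23 (7.70e-06). Adjusted over the list alone these counts were the same, and with an estimated correlation the adjusted p ranged from 0.106 to 0.71 over these lists. Nsd2 did not pass the test between tissues (-0.17 ± 0.11, edgeR adjusted p = 0.151). Yap1 (1.51 ± 0.10), Wwtr1 (1.69 ± 0.08), Lats1 (0.48 ± 0.13) and Lats2 (2.41 ± 0.11) were called higher in glomeruli. Of 16512 genes 12945 were called, 6388 higher and 6557 lower in glomeruli (edgeR).

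Genes called higher overlapped between the tissues more than independent lists would, while the fold changes over all genes were nearly uncorrelated. Among 13931 genes tested in both, 477 were called higher in both tissues, where independent lists give 332 (Fisher's exact test, two-sided, odds ratio 1.73, 95% interval 1.54 to 1.95, p = 1.11e-19). For lower calls 257 were shared, where independent lists give 294 (Fisher's exact test, odds ratio 0.835, 0.722 to 0.962, p = 0.0121). A further 313 genes were higher in glomeruli and lower in cortex (300.1 from independent lists; odds ratio 1.06, Fisher's exact test p = 0.376), and 297 the reverse (325 from independent lists). With an absolute log2 fold change of at least 1, 18 genes were higher in glomeruli and lower in cortex (7.01 from independent lists; odds ratio 3.22, Fisher's exact test p = 0.000117). These Fisher tests take genes as independent replicates, which they are not, and the labels do not say whether the tissues came from the same mice. Across genes the log2 fold changes of the tissues had a Pearson correlation of 0.0373 and a Spearman correlation of 0.00466. Genes called higher in both included Sox9 (2.69 in glomeruli and 2.35 in cortex), Trib3 (1.92 and 1.81), Asns (1.25 and 1.25), the class II gene H2-Aa (3.21 and 1.47) and Txnrd1 (0.80 and 0.32). Lats2 (-0.82 and -0.39), Myh11 (-3.93 and -0.75) and Per3 (-1.19 and -0.59) were called lower in both, and Osgin1 was called higher in glomeruli (3.76) and lower in cortex (-0.77).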

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

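The tests of explanations below were chosen after the results they bear on had been seen, except that of the counting of the tables, which was written before its result was seen.

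The effect of diabetes differed between glomeruli and cortex for 49 of 62 named genes and 15 of 28 lists by the interaction test (edgeR and camera). Apart from the 8 genes fixed by name, these genes were named for their large differences or small adjusted p in this comparison, so their share is set largely by that choice, and 5786 of all 16512 genes tested differed. As log2 differences, glomeruli minus cortex, and among the genes reported here, the effect was higher in glomeruli for Nsd2 (1.17), Lats1 (0.51), Prss22 (14.58), Plekhs1 (10.57), Psca (9.64), Slc22a29 (9.55), Msln (9.50), Car3 (6.03), Cyp21a1 (11.55), Trpm6 (3.69), Avpr2 (4.08), Scnn1b (4.50), Cd74 (2.14), Ccr2 (2.51), Cd2ap (1.00), Ass1 (2.30), Lrp2 (4.08), Slc6a19 (5.28), Miox (4.03), Hbb-bt (1.81), Slc4a1 (4.17), Hbb-bs (1.32) and Alas2 (1.43). It was lower in glomeruli for Yap1 (-0.59), Wwtr1 (-0.45), Lats2 (-0.43), Ccl7 (-9.47), Gdf6 (-9.02), Acta1 (-8.84), Itga11 (-8.72), Cxcl1 (-7.50), Jchain (-3.88), Il7r (-3.15), Cd4 (-2.40), Cd2 (-2.08), Lyz2 (-3.98), Cd68 (-1.51), Cspg4 (-1.28), Pdgfrb (-1.68), Serpine2 (-1.95), Rgs5 (-2.37), Foxc2 (-1.61), Kirrel (-1.37), Lmx1b (-0.90), Myh11 (-3.17), Mylk (-1.32), Tagln (-1.99) and Acta2 (-1.86). Genes near 0 in 1 of the groups, such as Prss22, Cyp21a1 and Gdf6, have fitted values that are no bounds. The lists that differed, with their median log2 difference, were higher in glomeruli for cholesterol and fatty acid synthesis (0.45), distal nephron and collecting duct markers (4.16), glucose handling (2.07), proximal tubule markers (3.58) and red blood cell markers (1.38), and lower for cell cycle (-0.55), extracellular matrix and fibrosis (-1.86), immediate early and heat shock genes (-1.81), inflammatory cytokines and NF-kB targets (-1.77), interferon response (-1.60), lymphocyte markers (-1.89), mesangial markers (-0.29), podocyte markers (-0.38), smooth muscle and renin cell markers (-1.38) and YAP and TAZ target genes (-0.62). With an estimated correlation none of these lists was called by camera.

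In 22 of 257 cortex groups of 4 libraries 1 library stood apart, its gap to the nearest other divided by the range of the group being over Dixon's 95% critical value. For independent values with a normal spread chance gives about 1 in 20, or 12.9 of these groups. These genes shared the same libraries, were named partly for their results in them, and were tested on CPM without logs. The 22 groups can therefore not be judged against that number. Groups of 3, as in glomeruli, were not tested. Control library 4 was highest for Cyp4a14 (gap share 0.946, 163 against 76.7 CPM in the next library), Cyp4a10 (0.879), Idi1 (0.879), Ash1l (0.854), Havcr1 (0.838, 3.08 against 1.33 CPM) and Bst2 (0.838), and lowest for Miox (0.894, 1218 against 2008 CPM). Control library 3 was highest for Cidec (0.991, 22.3 against 0.198 CPM), Ces1g (0.946), Plin4 (0.850), Akr1b7 (0.833) and Krt8 (0.831). Control library 1 was highest for Ighg2c (0.901) and lowest for Smyd2 (0.859). Diabetic library 1 was highest for Plin4 (0.901), G6pc (0.860), Itih2 (0.848), Nr1d2 (0.839) and Angptl7 (0.836). Diabetic library 4 was highest for Slc6a19 (0.850) and lowest for Txnrd1 (0.876), and diabetic library 2 was lowest for Scd2 (0.891).

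Nsd2 was higher in diabetic glomeruli, by a log2 fold change of 1.13. Over the scalings its lowest log2 fold change was 0.98, so scaling between libraries did not account for it. The highest cortex library held 42.4 CPM and the lowest diabetic glomerular sample 72 CPM on the same scaling. Admixed RNA of whole cortex could therefore not raise Nsd2 to the observed level if both tables counted it alike. The tables were counted differently, which can shift a single gene. Admixed material may also differ from whole cortex, as median shares in sample 1+4 were 4.20% by proximal and 23.9% by distal markers. The Nsd2 level of such material was not measured. More cycling cells would raise the cell cycle genes alike, and the upper quartile of their log2 fold changes was 0.32. An effect of diabetes on glomerular cells, or a change in the share of cell types within the glomerulus, remains open and was not tested.

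Of 19 tubular injury genes 7 were called higher in diabetic glomeruli, beside markers of mature tubules. If admixed tubule RNA had carried them at cortex levels, the 7 called genes would need a median share of 476, 515 and 345% of diabetic cortex RNA in samples 1+4, 2 and 3, and the lowest of these, 345.4%, is over any possible share. The upper quartiles of shares from proximal markers were 7.26, 0.0868 and 3.22%, and from distal markers 39.9, 1.89 and 16.3%. The 7 genes were those already called higher, and the shares compare tables that were counted differently, which can shift single genes. By their median, admixture of mature tubule RNA did not account for these 7 genes, although it may account for the tubule markers themselves. Single injury genes were not tested. Expression of these genes by glomerular cells, or by a kind of injured epithelium that cortex holds at a low share, remains open and was not tested.

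Among muscle and matrix genes called higher in control glomeruli than in control cortex, most stood higher than intact glomeruli in cortex would allow. From the lower quartile of 36 podocyte markers, glomeruli made up 8.53% of cortex RNA. Of 28 such genes, 24 were below the cortex level this needs (upper quartile of observed over needed level 0.65), Acta2 at 35.2 CPM against a needed 846. Glomeruli as present in cortex did not account for these 28 called genes as a set. Members not called higher in glomeruli were left out (2 of 10 smooth muscle and 3 of 25 matrix genes lower, 1 matrix gene not called). This choice favours low cortex levels, and the full lists were not tested against the bound. A difference in how the tables were counted would act on other genes too. Below the needed level were 85.7% of the muscle and matrix genes against 14.1% of 6360 other genes higher in glomeruli (Fisher's exact test, two-sided, p = 5.60e-17). This test takes genes as independent and uses the 24 genes that had shown the pattern. It cannot tell whether single genes were counted differently. A change or growth of cells after isolation cannot be told from the data. The bar set for it was over 50% of both the immediate early and the cell cycle genes below the needed level. This bar was missed (30.4 and 34.8%). Expression of these genes by other cortex cells, which was not measured, could keep them above the bound with or without such growth. That reading was adopted after the value was seen. No biological explanation was tested, and the lower values of these genes in diabetic glomeruli are relative to these control levels.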

How the results depend on the processing

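Of the alternatives, the 8 separate glomerular libraries were the design fixed beforehand, which became an alternative after the data were seen. Those chosen only after the data were seen were the near-identical pairs left out, diabetic glomerular libraries 1, 3 and 4 left out and cortex control libraries 3 and 4 left out. No named gene changed direction while called. Over all alternatives and named genes, glomerular values kept their side of the threshold in 3205 cases, lost it in 237 and gained it in 36. In cortex the numbers were 2714, 221 and 10, for the difference between tissues 1309, 43 and 4, and for the tissue contrast 1351, 0 and 6. List tests kept their side in 339 cases in glomeruli (29 lost, 10 gained) and 329 in cortex (21 lost, 12 gained). The causes of the following changes were not tested except where fewer samples or a stricter threshold entered by construction.

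In glomeruli 2611 genes (70.2% higher) passed an added absolute log2 fold change of at least 1, and 2293 with diabetic libraries 1, 3 and 4 left out, against 5717. Leaving out 1 library gave 4283 to 5661 and DESeq2 6680. In cortex the count was 924 (81.8% higher) with the fold change, 2401 (67.2% higher) with log2(FPKM + 1) without a filter, 3449 (61.8%) with its filter, and 2528 to 4715 with 1 library left out, against 3856. It was 2528, 2538 and 2542 without diabetic libraries 2, 3 and 4, and 3906 with control libraries 3 and 4 left out. With 1 library left out 5008 to 5827 genes were called for the difference between tissues and 12542 to 12989 for the tissue contrast. The odds ratio of genes lower in both tissues reversed from 0.835 to 1.42 with the fold change (4 genes shared), and that of genes lower in glomeruli and higher in cortex from 0.884, not past the threshold, to 1.47. The latter passed the threshold below 1 with DESeq2 (0.880), the replicate block (0.792) and the 8 separate libraries (0.816). That of genes higher in glomeruli and lower in cortex, 1.06 and not past the threshold, passed it with the fold change (3.22), DESeq2 (1.12) and the replicate block (1.20). With an estimated correlation 0 lists were called in glomeruli and 0 in cortex, against 11 and 15 by camera with a preset one. Fry, which does not compare a list with other genes, called 16 in cortex, keeping 14 of the 15 and adding 2. In glomeruli it called smooth muscle and renin cell markers (fry adjusted p = 0.000471) and YAP and TAZ targets (0.00591). Matrix genes and mesangial markers also passed there (fry adjusted p = 0.0427 each). Podocyte (0.0954), proximal (0.177) and distal tubule markers (0.0674) did not pass by fry, nor did the other glomerular lists. Fry called 4 in glomeruli, 5 were called with diabetic libraries 1, 3 and 4 left out, and with 1 library left out 9 to 15 in glomeruli and 14 to 18 in cortex.

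Same-numbered deviations showed no clear correlation, at -0.0578 to 0.107 in glomeruli and -0.103 to 0.0428 in cortex. Between tissues the correlations were -0.0906 to 0.0422 (control) and -0.0454 to 0.0924 (diabetic). Of 16 pairs, 3 were each best with their own number. Such values cannot show whether same-numbered libraries of the tissues came from the same mice, which the labels do not state. The tests of the difference and of the overlap between tissues did not allow for shared mice. With the replicate number as a block, 6992 genes were called in glomeruli (8 separate libraries) and 2375 in cortex. Low genes were recovered less in simulated counts: a 2-fold change was recovered in 5.88% of glomerular genes below the median level of 21.6 CPM and in 81.8% of those above it, and in 18.9 and 93.3% of cortex genes below and above 9.81 CPM. With 3 glomerular samples per group a simulated 1.5-fold change was recovered in 7.46% of cases over all levels. That simulation called 103 genes, against 5717 in the real glomerular fit. The adjustment sets a stricter cutoff on p where fewer genes change, so these shares can understate what the real fit recovers. Recovery at the real cutoff was not measured, so genes not called in the real fit cannot be taken as unchanged.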

Other observations

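The split tests, the p53 gene list and all tests of explanations were chosen after other results of these data had been seen, and the first p53 test itself was written before its genes' values were seen.

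Target genes of p53, the DNA damage response factor, were called higher in diabetic cortex more often than other genes. The list was written after Cdkn1a, Eda2r, Psrc1, Gdf15 and Btg2 had been seen to rise, and these 5 were kept out of the test. Of 24 other targets 16 were called higher and 1 lower (Rrm2b), 66.7% against 10.7% of the 19199 other genes (Fisher's exact test, two-sided, odds ratio 16.7, p = 9.36e-11). This test takes genes as independent. As a single list, not adjusted, camera gave p = 1.27e-10 with its preset correlation and p = 0.00108 with an estimated correlation, a test added after the result was seen. Phlda3 rose from 5.92 ± 1.54 to 34.6 ± 5.20 CPM (2.54 ± 0.19), Mdm2, which encodes the p53 ubiquitin ligase, from 44.1 ± 3.99 to 86.0 ± 7.45 CPM (0.96 ± 0.08), Zmat3 from 30.4 ± 2.25 to 63.6 ± 5.77 CPM (1.07 ± 0.08) and Bax from 25.8 ± 1.28 to 46.5 ± 3.22 CPM (0.85 ± 0.07; n = 4 each, edgeR adjusted p = 0.000110). Another 7 targets did not pass, among them Sesn1 (-0.05 ± 0.14), Perp (-0.03 ± 0.08) and Ddb2 (-0.02 ± 0.13). Activation of p53 targets in diabetic cortex is a hypothesis here, and whether p53 itself was active was not tested. Effects of streptozotocin and of the diabetic state on these genes cannot be told apart.

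Other splits of the same samples were fitted for each count. In glomeruli the real split called 5717 genes and the highest of the other 9 called 0; 10 splits are too few for a share under 0.05. For lists in glomeruli 5 of the 10 splits called as many as the real 11, with 17 as the highest of the others. In cortex 1 of 35 splits, the real one with 3856 genes, gave as many, against at most 1 gene in the others. This share, 0.0286, is the smallest that 35 splits can give. It also takes the libraries as separate animals, which the labels do not state. For lists in cortex 8 of 35 splits gave as many as the real 15, with 18 as the highest other, so chance could not be excluded for the number of lists called. For the tissue contrast 1 of 35 splits gave as many as 12945, with 7422 as the highest other. The 4 other splits with the most calls (5730 to 7422) kept all glomerular samples in 1 group with 1 cortex library, and so held most of the difference between tissues, and the rest gave at most 1 call. For the difference between tissues 1 of 60 drawn splits, the real one, gave as many as 5786, with 3882 as the highest other. That split relabelled all 6 glomerular samples and 2 cortex libraries, and so held the effect in glomeruli with its sign turned.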
